A study of Coturnix japonica with 24 samples.

How the data were processed

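Gene expression was measured in the mediobasal hypothalamus of 8-week-old male Japanese quail (Coturnix japonica), per the labels' protocols. The birds had spent 4 weeks under short days and were then kept there or moved to long days for 2 weeks. Tissue from 6 birds was collected every 4 h over 24 h, RNA from 3 birds was pooled per array, and biotin-labelled cRNA made from 5 ug of total RNA was hybridised to an Affymetrix array. The labels call the 2 arrays of a group biological replicates. The array carries chicken probes, so quail transcripts that differ from them in sequence can give a lower signal, and levels of different genes are not compared. The labels give no definition of ZT, which was read as hours after lights on.

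The deposited values are probe set intensity values on a linear scale, from 0.0275 to 13690, and the submitters' processing notes name GCOS 1.2. The algorithm settings and any scaling are not given in the sources used here. The deposited intensity values were not at a common level, since array medians differed by up to 1.93 times, over the limit of 1.5 set beforehand. Each array was therefore centred on its median log2 value. Of 38535 probe sets, 96 controls were left out. The pseudocount was 1.497, or 10% of the median of 14.97 over all arrays, because that median was below 16. Fold changes on the log2(intensity + pseudocount) scale understate the change of dim genes. Probe sets with a mean in the lowest 25% of the 38439 were left out, and 28829 were tested. No per-sample detection calls were used. Background was taken, after the data were seen, as the 95th percentile on each array of 746 probe sets whose names do not carry the chicken prefix.

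Gene names came from the platform annotation, which can be old. Of the 38439 probe sets, 27168 had 1 symbol, 177 several and 11094 none, and of those tested 21508, 135 and 7186. Of the 11830 tested genes, 9900 have a symbol that occurs in the gene table of the Coturnix japonica 2.1 assembly. No coordinates are given, since the array was designed on another species. A gene was represented by its probe set with the highest mean over 24 arrays, and probe sets with an _s_at or _a_at name can match several related transcripts.

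Tests used limma 3.58.1 in R 4.3.3. A model with a mean for each of the 12 groups (12 residual degrees of freedom) was fitted with lmFit and eBayes with a mean-variance trend. Contrasts gave the photoperiod effect as the mean over 6 times, the effect at each time, the light state contrast, and F tests of time of day in each photoperiod (5 degrees of freedom) and of the interaction. A second model fitted a 24 h cosine and sine in each photoperiod. Standard errors of amplitudes come from its moderated variance. P-values were adjusted by Benjamini-Hochberg over all probe sets tested, with 0.05 as the threshold. Since 2 arrays with different replicate numbers stand for a group, p-values measure the spread between pools of birds plus any difference between replicate numbers. 24 gene lists, named with their results in the comparisons, were tested with camera at a preset correlation of 0.01 and with an estimated one. Array measures were compared with 100000 permutations. Figures were drawn with matplotlib in Python.

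Named genes were chosen by a rule fixed before the data were examined: the 12 highest and 12 lowest changes among genes past the photoperiod test with the same direction at all 6 times, the 10 largest amplitudes among genes with a cosine in both photoperiods, the 8 smallest p of the interaction, cosine difference and light state tests, the 2 highest and 2 lowest changes at each time, and a fixed set of photoperiod, neuropeptide and clock genes. Where fewer than 5 passed, the 5 smallest p were named. From each list up to 4 members with the smallest p were named. Features outside the rule are marked where they stand, except further members of the gene lists, which are named with their list's results.

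The fits were tested on simulated data with 28829 probe sets and 100 changed ones per size. The changed ones were drawn only from the brighter probe sets, so recovery of dim ones was not measured. The simulated noise was independent between arrays and held no difference between array sets. A photoperiod change of 1 log2 unit was recovered in 68% and of 2 in 100%. A change at ZT14 alone was recovered in 23% at 1.5 log2 units and 85% at 3, an interaction in 6% at 1.5 and 35% at 3, and a cosine of amplitude 1 in 58% in short days and 55% in long days. A difference in cosine of 1 was recovered in 25%. Alternatives were other pseudocounts, quantile normalization, no centring, other filters, other variance models, array weights, the replicate number as a block, and leaving out each array. A pseudocount of 16, raising TSHB values under background to background, each array set alone and the counts of list members with a cosine under each alternative were added after the data were seen.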

Results

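Male Japanese quail were kept under short days (6 h of light and 18 h of dark) or moved to long days (20 h of light and 4 h of dark) for 2 weeks, and transcripts of the mediobasal hypothalamus, the part of the brain next to the pituitary stalk that holds the photoperiodic response, were measured on Affymetrix chicken arrays. Tissue was taken at 6 zeitgeber times (ZT), 4 h apart, read here as hours after lights on. Each of the 12 groups had 2 arrays, and each array held RNA pooled from 3 birds, so that 12 arrays stood for each photoperiod. The median deposited intensity of an array ranged from 10.9 to 21.05, and 38.1% to 49.6% of the probe sets on an array lay above background. The first array of a group was brighter than the second in 12 of 12 groups, by 1.23 to 1.85 times. The arrays numbered 1 and those numbered 2 are therefore also given apart, as array sets 1 and 2. Every group was present in both sets. Values below are intensities after each array was centred on its median, changes are long days minus short days on the log2(intensity + 1.497) scale with the moderated standard error (SE), and deviations after ± on intensities are standard deviations (s.d., n = 12). The number of arrays limits the precision of every value.

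The first comparison asked which transcripts differed between long and short days over all times of day. The clearest differences lay in the thyroid hormone pathway. TSHB, the beta subunit of thyrotropin, was at 223 ± 123 in long days and 9.22 ± 6.92 in short days, where only 1 of 12 arrays exceeded background against 12 of 12 in long days, a log2 change of 4.54 ± 0.29 (adjusted p = 2.4e-09). Its size depends on the floor, as it was 3.14 with a pseudocount of 16 and 3.32 with values under background raised to background. CGA, the alpha subunit that thyrotropin shares with the gonadotropins, rose from 567 ± 450 to 1528 ± 489, by 1.85 ± 0.13 (adjusted p = 5.6e-09). DIO2, the deiodinase that makes active thyroid hormone, rose from 63.0 ± 21.1 to 240 ± 36.7, by 1.97 ± 0.14 (adjusted p = 9.7e-09). DIO3, the deiodinase that inactivates thyroid hormone, fell from 1038 ± 293 to 54.6 ± 15.7, a change of -4.22 ± 0.17 (adjusted p = 1.8e-13). Within array set 1 and array set 2 the changes were 5.12 and 3.96 for TSHB, 1.91 and 1.79 for CGA, 2.05 and 1.89 for DIO2, and -4.19 and -4.25 for DIO3.

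**Figure D1:**
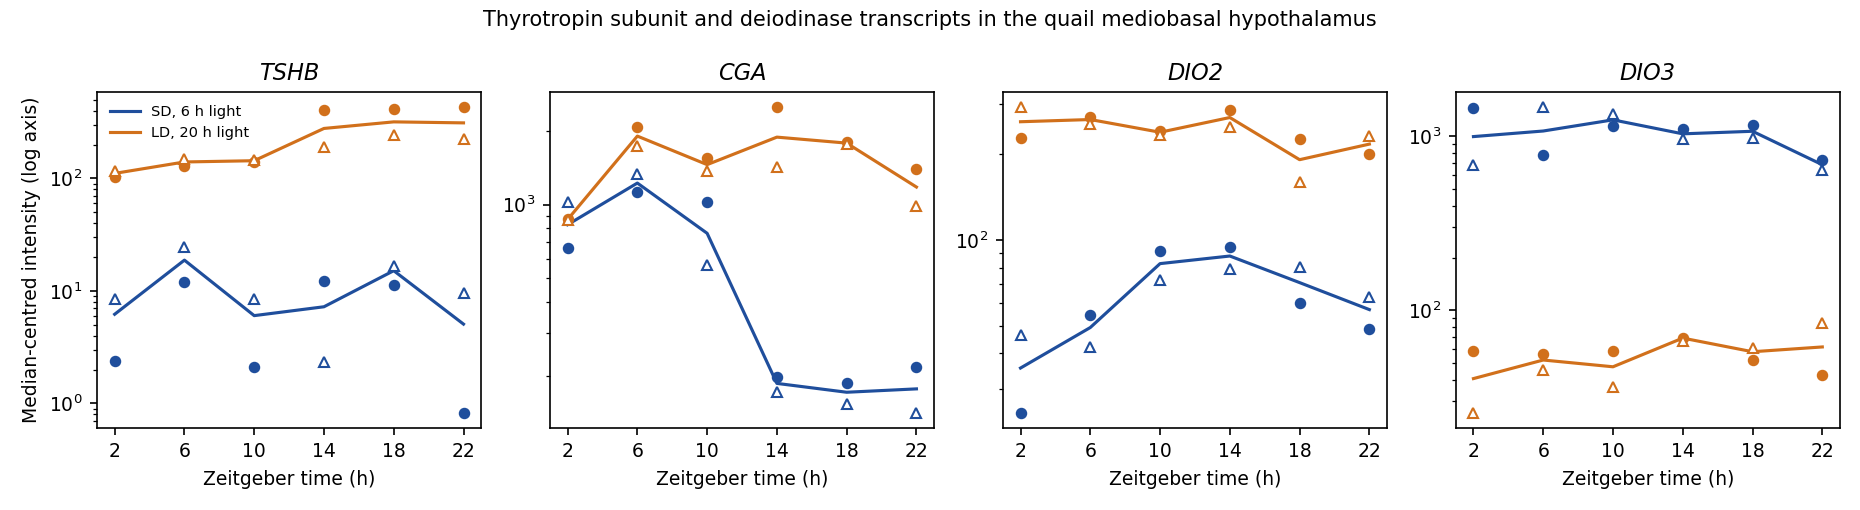
Median-centred intensity (log axis) of TSHB, CGA, DIO2 and DIO3 against zeitgeber time in hours, for short days (blue) and long days (orange); filled circles are arrays of set 1, open triangles arrays of set 2, and lines join the group means of log2 values. TSHB lies at 223 on average in long days and 9.22 in short days. CGA in short days meets the long-day level at ZT2 (845 against 867) and lies below it at the other times, most from ZT14 on.

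Altogether 38 of 28829 probe sets passed the photoperiod test at an adjusted p under 0.05, 22 higher and 16 lower in long days. They stood for 15 genes that rose and 10 that fell, and 9 of the probe sets had no single gene symbol. All 38 had the long-day mean on the same side of the short-day mean at all 6 times, 38 of 38 kept their direction in each array set, and 25 changed at least 2-fold. The 38 were chosen on these same arrays, so their shared directions are not independent support. At an unadjusted p under 0.05 there were 1563 probe sets, where 1442 would arise by chance. The count depended on scaling: quantile normalization gave 74 (53 higher and 21 lower), and uncentred values gave 12 (9 higher and 3 lower). The replicate number as a block raised it as well, as given below with the processing alternatives. Array set 2 alone gave 16.

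Among the other genes that rose were KLF9, a transcription factor induced by thyroid hormone (1.85 ± 0.14, adjusted p = 3.6e-08, from 159 ± 40.5 to 563 ± 91.7), and the neuropeptide gene CCK (1.34 ± 0.17, adjusted p = 8.8e-05). DNAJA1, a co-chaperone, rose by 1.201 ± 0.11 (adjusted p = 1.3e-06) and FKBP5, a glucocorticoid-induced co-chaperone, by 1.12 ± 0.19 (adjusted p = 0.0058). ETNPPL, an enzyme of phosphoethanolamine breakdown, rose by 1.47 ± 0.21, GREB1 by 1.09 ± 0.15 and the calcium-binding protein gene TESC by 1.08 ± 0.12. CYP19A1, which encodes aromatase, rose by 0.97 ± 0.19 (adjusted p = 0.026) and SEC14L1 by 0.96 ± 0.19 (adjusted p = 0.040). The remaining genes that rose, outside the fixed naming rule and named after their values were seen, were EPAS1 (0.55 ± 0.11), ABHD3 (0.80 ± 0.11) and PHKA1 (0.85 ± 0.14). Of the probe sets without a symbol, the 2 with the smallest p rose by 2.51 ± 0.19 and 1.67 ± 0.12, and were singled out after their values were seen.

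The genes that fell included POMC, the precursor of melanocortin peptides, which went from 275 ± 63.7 to 134 ± 32.1, a change of -1.04 ± 0.14 (adjusted p = 2.6e-04). The transcriptional repressor gene BCL6 changed by -1.09 ± 0.12, FABP7, a fatty acid-binding protein of radial glia and tanycytes, by -0.95 ± 0.14, and COLQ, the collagen tail of acetylcholinesterase, by -0.97 ± 0.14. FAM237A changed by -1.78 ± 0.21, ALS2L by -0.56 ± 0.11, the metalloproteinase inhibitor gene TIMP3 by -0.47 ± 0.09 and the kinase gene DCLK1 by -0.44 ± 0.08. LOC422926 changed by -2.71 ± 0.34 on a probe set above background on 1 of 12 long-day arrays and 11 of 12 short-day arrays. Its change ran from -3.20 to -1.45 under the alternatives, so the size is uncertain. The 2 other probe sets of LOC422926, both dimmer, were at 0.38 and 0.31. A dimmer probe set of COLQ was at 0.11, and 1 of 5 probe sets of DCLK1, 1 of 3 of GREB1 and 1 of 4 of SEC14L1 went the other way. Among the alternatives run, the calls of CYP19A1, SEC14L1, TIMP3 and ALS2L were lost in 17, 21, 18 and 19 of 35.

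**Figure D2:**
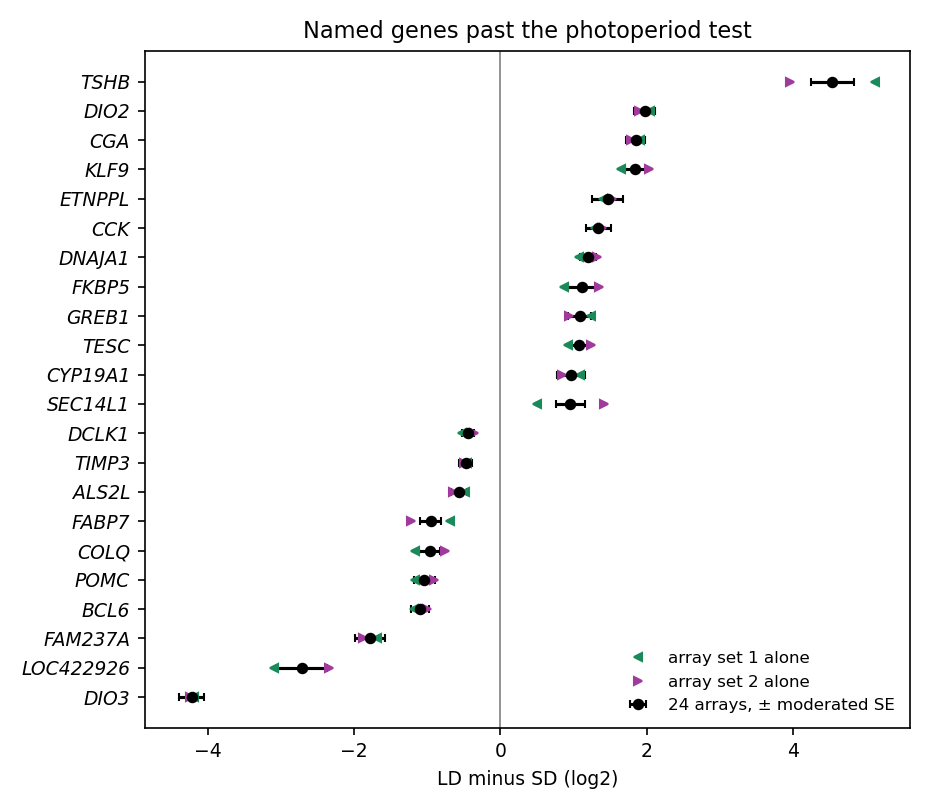
Long-day minus short-day log2 change of each of the 22 named genes past the photoperiod test (black points, bars ± the moderated SE over 24 arrays), with the change within array set 1 (green) and array set 2 (purple). The points run from -4.22 for DIO3 to 4.54 for TSHB, and both sets lie on the same side of 0 for each gene. The genes were chosen on both sets together.

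Several genes of the reproductive and feeding axes did not pass the test. GNRH1 was near background, above it on 5 of 12 short-day and 4 of 12 long-day arrays, with a change of -0.20 ± 0.44. NPVF, the gonadotropin-inhibitory hormone gene, was at 0.20 ± 0.18, VIP at 0.08 ± 0.09, AGRP at 0.12 ± 0.24 and NPY at -0.29 ± 0.09 (adjusted p = 0.55). EYA3 was at -0.08 ± 0.24, above background on 17 of 24 arrays, and the thyroid hormone transporter SLCO1C1 at 0.09 ± 0.17. The directions of GNRH1, AGRP, EYA3 and SLCO1C1 each turned when single arrays were left out. Of the clock and pineal genes fixed in advance, PER2 was at 0.50 ± 0.31, PER3 at -0.50 ± 0.25, CRY1 at -0.15 ± 0.14, ARNTL at 0.20 ± 0.18, CLOCK at 0.12 ± 0.14 and AANAT at 0.12 ± 0.29, the last with a direction that also turned. NR1D2 was at 0.53 ± 0.11 (adjusted p = 0.057), and it passed under some of the alternatives.

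Of 24 gene lists fixed in advance, 3 differed from the other genes in a competitive test (camera). In the thyroid hormone and pars tuberalis list, 3 of 18 measured genes rose and 1 fell, and adjusted over the list alone 5 rose (TSHB, CGA, DIO2, CHGA and MTNR1B) and 2 fell (DIO3 and TSHR). The list's adjusted p was 0.0055, and its adjusted p = 0.034 with an estimated correlation. The study may have chosen some of these genes on these arrays, so the count is not independent evidence of direction. The list median was 0.08, at -0.15 within set 1 and 0.33 within set 2. Ribosomal protein genes were lower in long days as a group (adjusted p = 5.8e-11, and adjusted p = 0.034 with an estimated correlation). Their median was -0.12 over 68 genes, 12 of them positive, and -0.15 and -0.09 within the sets, or -0.07 after quantile normalization and -0.15 uncentred, with none past the test over all probe sets and 4 lower adjusted over the list alone (RPL4, RPL12, RPL30 and RPLP0). Immediate early genes were higher (adjusted p = 0.0080), a call lost with an estimated correlation (adjusted p = 0.35). None of the 19 passed over all probe sets, and CREM did adjusted over the list alone, at 0.44 ± 0.11, with DUSP1 at 0.42 ± 0.16, MYC at 0.55 ± 0.21 and HOMER1 at 0.29 ± 0.13.

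The 21 other lists did not pass. In the thyroid hormone responsive list of 8 measured genes (adjusted p = 0.11), KLF9 rose and DIO3 fell, with RELN at -0.27 ± 0.16 and SHH at -0.34 ± 0.20. In the reproductive list of 19 (adjusted p = 0.11), CYP19A1 rose, and PRLR was at 0.46 ± 0.14, ESR2 at -0.44 ± 0.22 and VIPR1 at 0.54 ± 0.34. In the feeding peptide list of 26 (adjusted p = 0.38), CCK rose and POMC fell, and DDC was at -0.66 ± 0.17 and MC4R at 0.50 ± 0.15. DNAJA1 and FKBP5 rose in the heat shock and glucocorticoid list of 22 (adjusted p = 0.11), with HSPD1 at -0.33 ± 0.13 and HSPA2 at -0.33 ± 0.17. The clock list (adjusted p = 0.052) held no called gene among 19, with ARNTL2 at 0.88 ± 0.39 and NPAS2 at 0.35 ± 0.18 besides NR1D2 and PER3. Nor did endoplasmic reticulum folding (adjusted p = 0.11; CRELD2 0.37 ± 0.19, HSPA5 0.14 ± 0.07, HERPUD1 0.30 ± 0.16 and HSP90B1 0.21 ± 0.11), cholesterol synthesis (adjusted p = 0.11; PMVK -0.50 ± 0.21, STARD4 0.60 ± 0.30, INSIG1 -0.66 ± 0.37 and FDPS -0.59 ± 0.35), glycolysis (adjusted p = 0.22; GPI 0.27 ± 0.10, PDK4 0.75 ± 0.44 and TPI1 0.20 ± 0.14) or oxidative phosphorylation (adjusted p = 0.52; NDUFB6 -0.80 ± 0.32, UQCR11 -0.45 ± 0.19, COX8A -0.54 ± 0.23 and NDUFB10 0.47 ± 0.20). The neurite list, with no called gene, had an adjusted p of 0.14. After quantile normalization the clock list (adjusted p = 0.019) and the heat shock list (adjusted p = 0.032) passed, and the latter also with all probe sets of each gene (adjusted p = 0.031), each call lost with an estimated correlation (adjusted p = 0.13, 0.16 and 0.57). With the replicate number as a block the clock list passed camera as well (adjusted p = 0.048), a call also lost with an estimated correlation (adjusted p = 0.29).

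Markers of cells that a hypothalamic dissection can hold were listed as well, and none of these lists passed. Under alternatives 3 did: the neuron list (adjusted p = 0.0055) and the connective tissue list (adjusted p = 0.043) after quantile normalization, and the microglia list (adjusted p = 0.0083) with all probe sets of each gene. With an estimated correlation in those settings their adjusted p values were 0.16, 0.13 and 0.20. POMC was the one called gene of the anterior pituitary list (adjusted p = 0.11), with GH at 0.08, PRL at 0.25, TBX19 at -0.42 ± 0.22, POU1F1 at -0.64 ± 0.36 and PCSK2 at 0.08 ± 0.10. FABP7 was that of the tanycyte list (adjusted p = 0.11), with VIM at -0.22 ± 0.09, NES at -0.30 ± 0.22 and SLC1A3 at -0.07 ± 0.07. No gene changed in the lists of astrocytes (adjusted p = 0.42; SLC1A2 0.59 ± 0.22, ID3 0.67 ± 0.29, CLU -0.19 ± 0.10 and SPARCL1 -0.45 ± 0.31), oligodendrocytes (adjusted p = 0.11; PDGFRA -0.36 ± 0.21, FA2H -0.22 ± 0.17, ASPA -0.16 ± 0.17 and NKX6-2 -0.19 ± 0.21) or neurons (adjusted p = 0.11; STMN3 0.53 ± 0.17, SYN2 0.29 ± 0.11, GAD1 0.49 ± 0.25 and SLC17A6 0.31 ± 0.18). The same held for microglia and immune cells (adjusted p = 0.11), with CD8A at -0.63 ± 0.28, CSF1R at -0.23 ± 0.11, C1QB at -0.41 ± 0.26 and CD74 at -0.33 ± 0.22. Endothelium (adjusted p = 0.11) had SLC2A1 at 0.75 ± 0.26, FLT1 at 0.46 ± 0.21, EGFL7 at 0.26 ± 0.19 and VWF at 0.32 ± 0.26, and blood cells (adjusted p = 0.80) had HBZ at 0.59 ± 0.34, HBE at -0.21 ± 0.38, HEMGN at -0.15 ± 0.32 and SLC4A1 at -0.08 ± 0.20. In the choroid plexus list (adjusted p = 0.11) IGFBP2 was at -0.21 ± 0.10, AQP1 at -0.39 ± 0.20, SLC4A2 at -0.20 ± 0.24 and TTR at -0.22 ± 0.27. In connective tissue (adjusted p = 0.11) PTGDS was at 0.52 ± 0.13, FN1 at -0.39 ± 0.13, COL1A1 at -0.65 ± 0.22 and TAGLN at -0.43 ± 0.22, and in retina and pineal (adjusted p = 0.11) ARR3 at -1.14 ± 0.37, OPN1LW at -0.77 ± 0.38, SAG at -0.63 ± 0.36 and PDE6G at 0.68 ± 0.39. The test and the median differed in sign for the tanycyte, blood and glycolysis lists, and SLC1A3, HBE, HEMGN and SLC4A1 turned direction under alternatives. RNA quality was compared as well. The log2 ratio of 3' to 5' signal of the ACTB control was 1.84 ± 0.15 in long days and 1.69 ± 0.17 in short days (s.d., n = 12, 2-sided permutation p = 0.023, adjusted p = 0.115 over 5 measures), and that of GAPDH was 0.22 ± 0.10 and 0.21 ± 0.11 (permutation p = 0.74).

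The next comparisons took each time of day on its own, with 2 arrays against 2. DIO3 was lower in long days at all 6 times, by -3.48 at ZT22 to -4.72 at ZT10 (SE 0.41 at each). DIO2 passed at ZT2 (2.88 ± 0.35) and ZT6 (2.43 ± 0.35), and TSHB at ZT10, ZT14, ZT18 and ZT22, with 5.94 ± 0.72 at ZT22, or 3.94 there for TSHB with a pseudocount of 16. At the other times DIO2 was also higher, by 1.44 at ZT18 to 1.94 at ZT22, without passing. TSHB was higher by 4.16 at ZT2 and 2.90 at ZT6, without passing either. Neither gene passed the interaction test, so these calls do not show a rise limited to certain times. Of 35 alternatives, 1 and 6 lost the DIO2 calls at ZT2 and ZT6, and 5, 2, 7 and 0 the TSHB calls at ZT10, ZT14, ZT18 and ZT22. CGA did not differ at ZT2 (0.07 ± 0.31), and its changes of 0.64 ± 0.31 at ZT6 and 0.93 ± 0.31 at ZT10 did not pass. It passed at ZT14 (3.34 ± 0.31), ZT18 (3.38 ± 0.31) and ZT22 (2.74 ± 0.31), the last lost in 2 of 35, while the DIO3 calls were lost in 0. The counts of probe sets past the test were 2 at ZT2, 4 at ZT6, 4 at ZT10, 8 at ZT14, 5 at ZT18 and 3 at ZT22. NEO1 was called at ZT10 (3.76) and KLF9 and DNAJA1 at ZT14 (2.16 and 1.87). NEO1 was named after its values were seen. Quantile normalization gave 11 at ZT2, 7 at ZT6 and 9 at ZT10, and uncentred values 1, 1 and 2 there, 3 at ZT14 and 2 at ZT18. A group left with 1 array holds only 1 array set, so a difference between sets enters its contrast. The set 2 array of long-day ZT14 had the lowest median Spearman correlation with the other arrays of all 24 (0.71). Its log2 3' to 5' ratios of ACTB (2.21) and GAPDH (0.37) were the highest. Counts of probe sets past the test depended on single arrays of the same time as well. Without the set 1 array of short days they were 27 at ZT2, 17 at ZT6, 72 at ZT10, 81 at ZT14 and 20 at ZT22, and without that of long days 6 at ZT2, 8 at ZT6, 11 at ZT10 and 344 at ZT14. Without the set 2 array of short days they were 1 at ZT6, 2 at ZT14 and 7 at ZT22, and without that of long days 1 at ZT6 and 3 at ZT18. Arrays of another time moved the count to 2 at ZT6 (set 2, long-day ZT2), to 8 at ZT10 (either short-day ZT14 array) and to 7 at ZT10 (set 1, long-day ZT14).

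The question of whether transcripts followed the time of day was answered within each photoperiod. In short days, CGA followed a 24 h cosine with a log2 amplitude of 1.66 and a peak at 5.97 h (adjusted p = 6.0e-07), falling from 1226 ± 145 at ZT6 to 171 ± 23.6 at ZT18 (s.d. of 2 arrays). HSPA2, a heat shock protein gene, had an amplitude of 1.45 with a peak at 2.99 h (adjusted p = 0.0059) and stood at 1459 ± 770 at ZT2 and 154 ± 59.5 at ZT10. The clock gene NR1D2 had an amplitude of 0.81 with a peak at 20.5 h (adjusted p = 0.0034). DNAJA1 (0.70, peak 3.66 h) and the endoplasmic reticulum chaperone HSP90B1 (0.72, peak 5.23 h) passed as well, both at an adjusted p of 0.024, calls lost in 8 and 9 of 35 alternatives. Those of HSPA2 and NR1D2 were lost in 3 each and that of CGA in 0. In all, 6 probe sets passed in short days, 5 of them named genes (2 uncentred or without the variance trend, 3 with a pseudocount of 16), and 0 in long days, where 1163 had an unadjusted p under 0.05 in limma's test and 1442 would by chance. A test of the 6 means gave 6 in short days, among them HSPA5 and NEO1, and 0 in long days, where 987 had an unadjusted p under 0.05, again fewer than the 1442 of chance. The short-day count was 0 with uncentred values and 3 without the variance trend or with a pseudocount of 16. It was 19, 12, 22 and 36 without the set 1 array of short-day ZT2, ZT6, ZT10 and ZT14, and the long-day count was 93 without that of long-day ZT14. The genes nearest to the threshold in long days were CCL4, SLC25A25, ARHGEF37, PADI2 and CBX7, with amplitudes of 1.38, 1.03, 1.25, 1.16 and 0.70, none of them past it. No gene passed in both photoperiods, and those with the smallest p in both were CBX7, ARNTL, NR1D2, P3H2 and LOC420160.

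Clock genes were then taken as a list of 19 measured genes. Adjusted over the list alone, 6 had a cosine in short days (ARNTL, CRY1, NR1D2, NPAS2, NFIL3 and BHLHE41) and 2 in long days (ARNTL and NR1D2). Over all probe sets these counts were 1 and 0, and uncentred values gave 2 and 0 adjusted over the list alone. The long-day count was also 0 with a pseudocount of 16 or 4 times larger, without the variance trend, and without any of 5 single long-day arrays (both at ZT2, set 1 at ZT10 and ZT14, set 2 at ZT22). ARNTL, the partner of CLOCK, peaked at 9.70 h in short days (amplitude 0.82 ± 0.17) and at 14.2 h in long days (0.67 ± 0.17). CRY1, a repressor of the clock, peaked at 6.72 h (0.77 ± 0.13) and at 10.9 h (0.39 ± 0.13), and NR1D2 at 20.5 h (0.81 ± 0.11) and 0.77 h (0.42 ± 0.11). The cosine differed between photoperiods, adjusted over the list alone, for NR1D2 (adjusted p = 0.0068), ARNTL (0.041) and CRY1 (0.041), while no clock gene passed over all probe sets. That count of 3 fell to 0 with uncentred values, without the variance trend or with a pseudocount of 16, and to 1 without any of 6 single arrays, the set 2 arrays of long-day ZT6 and ZT18 and of short-day ZT2, both short-day ZT18 arrays and the set 1 array of short-day ZT6.

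**Figure D3:**
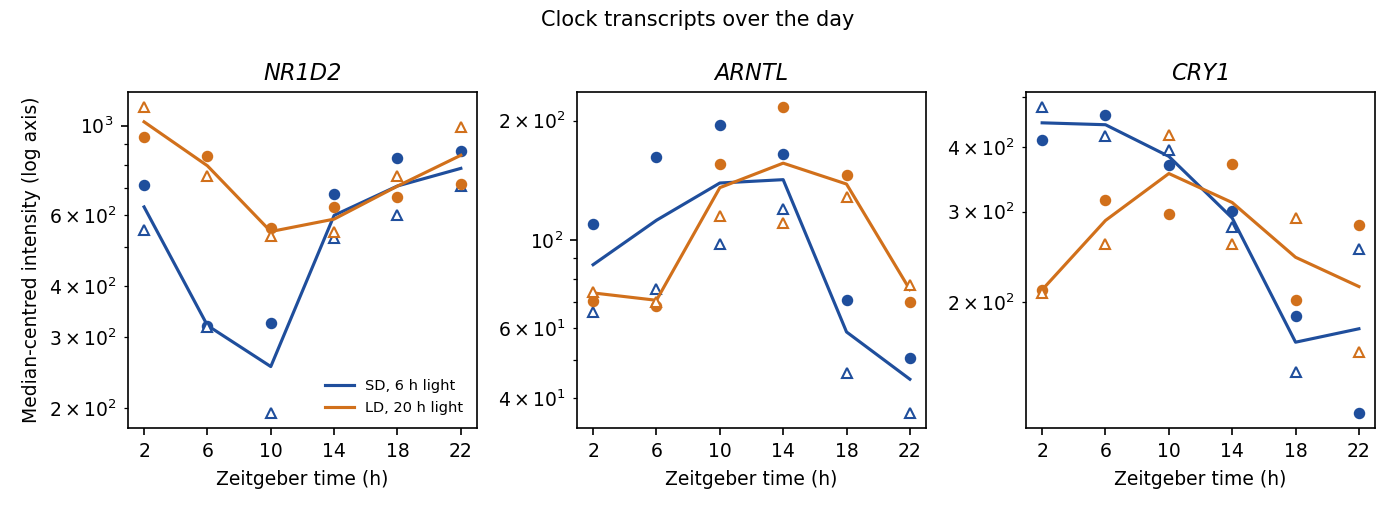
Median-centred intensity (log axis) of NR1D2, ARNTL and CRY1 against zeitgeber time in hours, for short days (blue) and long days (orange); circles are arrays of set 1, triangles arrays of set 2, and lines join the group means of log2 values. The fitted ARNTL peak lies at 9.70 h in short days and 14.2 h in long days.

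Of 22 measured genes of the heat shock and glucocorticoid list, 9 had a cosine in short days and 0 in long days, adjusted over the list alone, and 2 and 0 over all probe sets. HSP90AA1 had an amplitude of 0.38 ± 0.08 with a peak at 3.35 h and BAG3 of 0.68 ± 0.13 at 3.21 h, whereas RBM3, a cold-induced RNA-binding protein gene, had 0.83 ± 0.21 at 16.8 h. Of 24 endoplasmic reticulum folding genes, 5 had a cosine in short days (HSPA5, HSP90B1, HERPUD1, PDIA6 and P4HB) and 0 in long days, adjusted over the list alone, with HSPA5 at 0.53 ± 0.10 and a peak at 4.02 h. The difference between photoperiods, adjusted over the list alone, passed for 6 heat shock list genes and 3 folding genes. FKBP5, 1 of the 6, had the larger amplitude in long days (0.73 against 0.34). Both counts fell to 0 with uncentred values or without the variance trend, which left 2 and 5 heat shock list genes and 1 and 3 folding genes with a cosine in short days, and they ranged from 2 to 9 and from 1 to 3 as single arrays were left out.

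**Figure D4:**
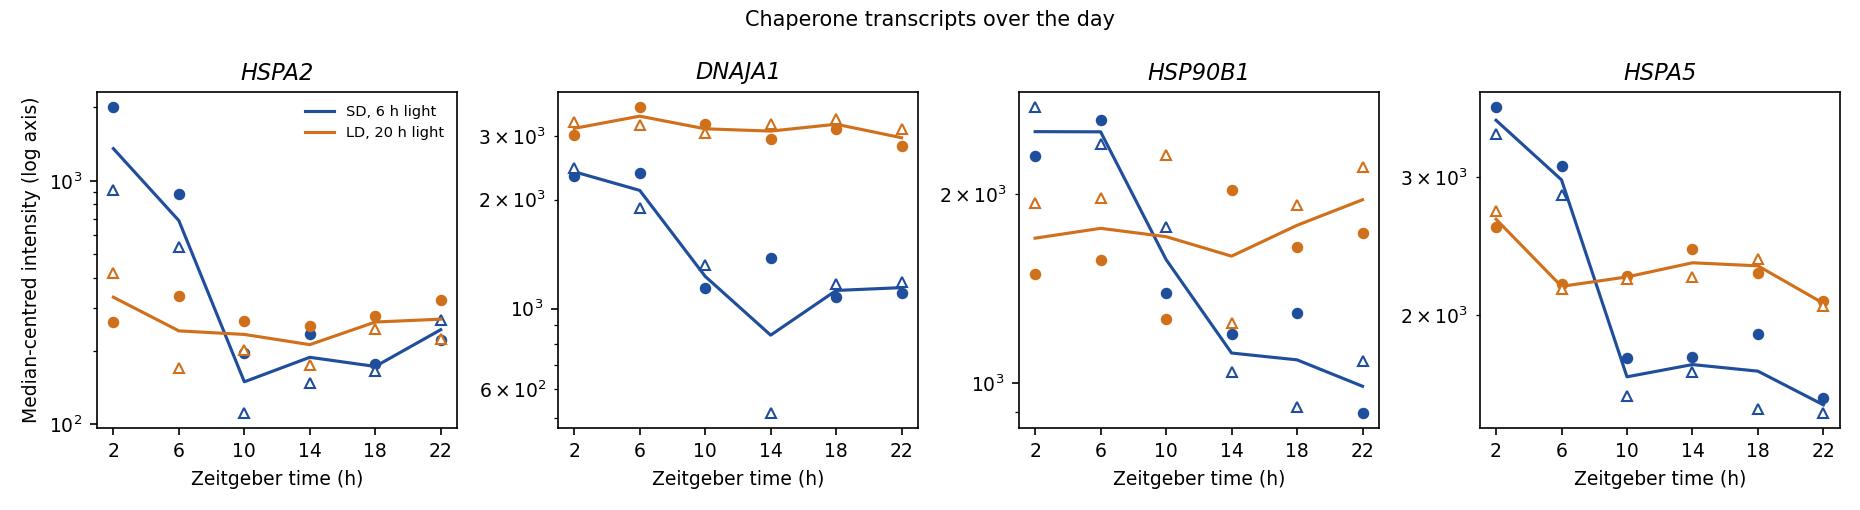
Median-centred intensity (log axis) of HSPA2, DNAJA1, HSP90B1 and HSPA5 against zeitgeber time in hours, for short days (blue) and long days (orange); circles are arrays of set 1, triangles arrays of set 2, and lines join the group means of log2 values. In short days the 4 genes are highest at ZT2 or ZT6, with HSPA2 at 1459 at ZT2 and 154 at ZT10.

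The last comparisons asked whether the photoperiod difference itself changed over the day. CGA passed the interaction test (adjusted p = 0.0013), its change ranging over 3.31 log2 units between times, and the test of a difference in cosine (adjusted p = 1.8e-04). The CGA interaction call ended with uncentred values, without the variance trend and with a pseudocount of 16 (adjusted p = 1, 0.32 and 0.11), and the cosine difference with uncentred values (adjusted p = 0.24). A probe set without a gene symbol passed both. The genes next in order did not pass the interaction test: HSPA2, SNW1, GPX4 and HSPA5, with 0.986 as the lowest adjusted p, though SNW1 did after quantile normalization (adjusted p = 0.029). The interaction count of 2 was 7, 6, 6 and 5 without the set 1 array of short-day ZT2, ZT6, ZT10 and ZT14, and 32 without that of long-day ZT14. LOC420160, NR1D2, HSP90B1 and CD88 did not pass the cosine difference over all probe sets. A contrast between the times lit only in long days (ZT10, ZT14 and ZT18) and the times with the same light in both (ZT2 and ZT22) called only that probe set (1.99). GPX4, NWD2, NEK8, CGA and ADGRG3, which came next, did not pass. In the simulated data this contrast recovered 6% of changes of 1 log2 unit and 56% of those of 2, so it can miss many differences. The heat shock list was higher in this contrast (adjusted p = 0.0083), a call lost with an estimated correlation (adjusted p = 0.92), and the 23 other lists did not pass.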

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

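The tests of explanations here were chosen after the results were seen. The results drew attention because a test of the difference between short and long days over the day passed. CGA had an interaction at an adjusted p of 0.0013 and a cosine difference at 1.8e-04, and a probe set without a gene symbol had 0.0018 and 7.3e-05, with 0.0017 in the light state contrast. Uncentred values ended these calls. Adjusted over single lists, the cosine differed for NR1D2 (0.0068), ARNTL (0.041) and CRY1 (0.041), for HSPA2 (0.011), DNAJA1 (0.011), HSP90AA1 (0.040), SERPINH1 (0.040), RBM3 (0.040) and FKBP5 (0.041), and for HSP90B1 (0.013), HERPUD1 (0.020) and HSPA5 (0.039). In the thyroid list CGA had 2.3e-07 and DIO2 0.041. CLIC6, above background on 5 of 24 arrays, had 0.021 in the choroid plexus list. These values were not adjusted across the 24 lists.

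TSHB and CGA were both higher in long days. A larger share of pituitary tissue in the long-day pools would raise both by the same factor if both came only from that tissue in constant proportion. With values under background raised to background, which can only lower its change, TSHB still rose by 1.47 ± 0.16 log2 units more than CGA. This would argue against tissue share as the sole source only if that condition held, which the profiles did not show. In short days CGA fell from 1226 at ZT6 to 171 at ZT18, while TSHB was at 18.3 and 13.8, near background. Their proportion could not be followed there, so the comparison does not decide on tissue share. The anterior pituitary list had a median change of -0.03 over 11 measured genes, 5 of them positive. Centring each array on its median took out any overall difference in brightness before these changes were computed. Without centring, the median change of all tested probe sets was -0.0398 (SE 0.136). That shows only that the deposited long-day arrays were not clearly brighter, and decides nothing about TSHB and CGA. A change in expression with photoperiod and a difference in tissue share both remain as hypotheses.

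The fitted peaks of the 6 clock genes with a cosine in short days lay later in long days in 6 of 6, by a median of 4.26 h (bootstrap SE 0.704 h), though only ARNTL and NR1D2 (4.496 ± 1.26 h and 4.28 ± 1.15 h) had a cosine in long days as well, so the other 4 peaks there are uncertain. Photoperiod labels were exchanged within ZT in all 46656 ways. As large a summed phase shift over the 19 measured clock genes, in either direction, arose in a share of 1.3e-04 (exact permutation test). This argues against chance, though the share was not corrected for choosing this list after the results were seen. The median delay was 5.19 h in set 1 and 3.92 h in set 2, so both sets held it. Since every group was present in both sets, a constant difference between sets could not produce it. Lights-off came 14 h later in long days, and the delay fell short of that by a difference of -9.74 h, while it also differed from 0 h. The difference from 14 h could not decide on lights-off, since delays were folded onto the 24 h cycle and could not reach 14 h. A shift of 14 h would have shown as earlier peaks instead, whereas the fitted peaks lay later in 6 of 6. That direction argues against peaks set by lights-off alone, and the difference from 0 h against peaks set by lights-on alone. No other explanation was tested.

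Genes of the heat shock list had a larger amplitude in short days in 16 of 22, with means of 0.49 and 0.22. A mean difference as large arose in a share of 0.0036 of the 46656 exchanges (exact permutation test). The list was singled out on the same arrays, and the share was not corrected for that choice, so it cannot decide on chance. The median difference was 0.14 in set 1 and 0.24 in set 2, so both sets held it. By the design, a constant difference between sets could not produce it. RBM3, which cold induces, peaked 10.3 h from the median peak of the 8 other members with a cosine, but as 1 gene singled out for that peak it decides nothing on a daily cycle of body temperature. That cycle, which was not measured here, handling at collection and chance stay open.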

How the results depend on the processing

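The pseudocount of 16 and the array sets alone were chosen after seeing the data. Exchanging photoperiod within ZT gave as many as the real 38 probe sets in 1 of 100 splits, the real one included, with 3 as the highest other, which is fewer than the 5 of 100 set as the bound for chance. None of the 44 named results past the threshold turned direction under the alternatives run, and 26 changed side in at least 1. Of 141 not past it, 11 turned direction. Both totals include amplitudes and ranges, which cannot be negative and so could not turn. Dim genes are limited by signal over background.

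Probe sets past the photoperiod test numbered 74 after quantile normalization (36 of the 38 shared), 12 uncentred (12 shared), 25 with a 2-fold minimum and 16 in array set 2 alone, and 32 to 46 as single arrays were left out. The replicate numbers were not used as pairs in the main model. Residual correlations of the 66 pairs ran from 0.010 to 0.10, so all were positive, with 3 over the limit of 0.1. Of 24 arrays, 12 correlated best with an array of their own number. The log2 GAPDH 3' to 5' ratio ran from 0.062 to 0.24 in set 1 and 0.26 to 0.37 in set 2, without overlap. A difference between the sets thus stays in the spread of the main model. With the replicate block there were 76 (38 shared) for photoperiod, 8 at ZT2, 8 at ZT6, 8 at ZT10, 6 at ZT22, and 11 each for time of day and cosine in short days. Quantile normalization gave 11 at ZT2, 7 at ZT6 and 9 at ZT10, 7 gene lists for photoperiod, and turned SLC1A3 to 0.0016. Uncentred values gave 1 at ZT2, 1 at ZT6, 2 at ZT10, 3 at ZT14, 2 at ZT18, 2 for the cosine in short days, and 0 for the light state, time of day in short days, interaction and cosine difference. Without the variance trend there were 1 at ZT6, 2 each at ZT10, ZT14 and ZT18, 3 for time of day and 2 for the cosine in short days, and 0 for light state and interaction. The pseudocount of 16 gave 1 at ZT6, 2 at ZT10, 3 each at ZT14, ZT18, time of day and cosine in short days, and 0 for light state and interaction. A pseudocount 4 times larger gave 2 at ZT6. Array weights gave 5 at ZT14 and 5 at ZT22. All probe sets of each gene gave 5 gene lists for photoperiod, and an estimated correlation gave 0 for the light state. The cause of these shifts was not tested.

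With single arrays left out, the lone array being assumed to vary like the other groups, counts ran from 2 to 27 at ZT2, 1 to 17 at ZT6, 3 to 72 at ZT10, 2 to 344 at ZT14, 3 to 7 at ZT18, 3 to 20 at ZT22, 5 to 36 and 0 to 93 for time of day in short and long days, 2 to 32 for the interaction and 1 to 3 for the light state. The highest came without the set 1 array of short-day ZT2, ZT6, ZT10 and ZT22, of long-day ZT14 (ZT14, long-day time of day and interaction) and ZT18, of short-day ZT14 (short-day time of day) and of short-day ZT2 (light state). The array then left at long-day ZT14 was the one with the lowest correlation and the highest ACTB and GAPDH ratios given above. Whether that raised the counts was not tested. Changes that turned ran from -0.0314 to 0.27 for AANAT, -0.0667 to 0.30 for AGRP, -0.18 to 0.41 for CD88, -0.18 to 0.0119 for EYA3, -0.42 to 0.0218 for GNRH1, -0.43 to 0.0070 for HBE, -0.30 to 0.0044 for HEMGN, -0.20 to 0.0337 for SLC4A1, -0.0344 to 0.22 for SLCO1C1 and -0.0916 to 0.0515 for SNW1.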

Other observations

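The list of neurite and perineuronal structure did not pass its test, but 5 of its 30 genes did adjusted over the list alone. ACAN, the core protein of perineuronal nets, was higher (1.27 ± 0.28, adjusted p = 0.0041) and DCX (-0.38 ± 0.11), EFNA5 (-0.45 ± 0.12), NRP2 (-0.53 ± 0.18) and STMN1 (-0.20 ± 0.07) were lower. ACAN lay above background on 13 of 24 arrays. None passed over all probe sets, where ACAN had an adjusted p of 0.086. Among dimmer probe sets, that of ACAN (-0.12), 1 of 2 of EFNA5 (0.29), 1 of 2 of NRP2 (0.21) and 1 of 3 of DCX (0.07) went the other way.

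Among feeding and neuroendocrine peptides and receptors, adjusted over their lists alone, MC4R was higher (0.50 ± 0.15) and DDC, an enzyme of dopamine synthesis (-0.66 ± 0.17), and NPY (-0.29 ± 0.09) were lower. The 2 dimmer probe sets of DDC were at 0.35 and 0.66, in the other direction. PRLR, the prolactin receptor gene, was higher at 0.46 ± 0.14. PTGDS, a prostaglandin synthase, was higher in the connective tissue list (0.52 ± 0.13). Over all probe sets none of these passed, with adjusted p values of 0.47 for MC4R, 0.25 for DDC, 0.55 for NPY, 0.53 for PRLR and 0.18 for PTGDS.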
